A study of Mus musculus with 4 samples.

How the data were processed

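The series measured RNA bound to phosphorylated ribosomes in mouse hypothalamus. Per the labels, C57Bl/6J mice aged 12 weeks received an injection of 2 M NaCl (325 uL) or of phosphate-buffered saline (vehicle), had their water removed, and were killed 2 h later. Ribosomes were immunoprecipitated (IP) from homogenised hypothalamus with an antibody against ribosomal protein S6 phosphorylated at residues 244 and 247, and total RNA of the homogenate served as input. Each of the 4 samples (2 salt, 2 control) has 1 IP array and 1 input array, 8 Illumina BeadArrays in all. The RNA was amplified with an Ovation kit and biotin-labelled, per the labels' protocols. GenomeStudio is named in the submitters' processing notes, without a version. The labels do not say whether a sample is 1 animal or a pool, so p-values measure the spread between these samples only.

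The authors deposited probe intensities on a linear scale with a detection p-value per probe and array, per the file headers. Undetected probes had median intensities between 99.3 and 112.2, so no background had been subtracted. The authors also deposited the IP/input ratio of each sample. The deposited ratio equals the quotient of the deposited intensities (largest relative gap 1.6e-09), and both deposited tables hold the same ratios. The authors' deposited table adds the log2 of the mean salt ratio over the mean control ratio. These ratios, with neither background correction nor scaling, served as an alternative.

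Intensities were background-corrected and quantile-normalized over all 8 arrays with limma's neqc steps (limma 3.58.1 in R 4.3.3), which infer the negative controls from the detection p-values, with an offset of 16, and were put on the log2 scale. Probes with a detection p under 0.01 on at least 2 arrays were kept, 14199 of 25697 probes and 10184 genes. Of the 25697 probes, 20736 carried a current mouse symbol, 3874 were renamed through an older symbol that pointed to 1 gene, and 1087 kept the name in the file. The table used for names follows assembly GRCm38.p6; no coordinates are printed. A gene with several probes is represented by the probe with the highest mean over all arrays, and counts of calls are counts of probes.

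The log2 IP minus log2 input of each sample was fitted with limma (lmFit, eBayes) for the 2 groups, with 2 residual degrees of freedom before moderation. It gave the IP/input ratio of salt against control and of each group against 0. The log2 levels of all 8 arrays were fitted with 4 group means and 4 residual degrees of freedom, and gave the change of the input and of the IP. Errors are standard errors (SE) of these fits, n is 2 samples per group throughout, tests are two-sided, and p-values were adjusted by Benjamini-Hochberg over the 14199 probes with a threshold of 0.05. A probe that passes alone needs an unadjusted p of 3.52e-06. Where no array of a group detected a probe, the fold is given as "at least": the brighter group's mean over the dim group's mean of, per array, the lowest detected signal or the probe's own value if higher. List medians are also given "with bounds", with each such member at its bound, or at 0 where neither group was detected or no bound was left.

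Lists of genes were fixed before the data were examined: immediate early genes, magnocellular genes, other neuropeptides, neuron classes, suprachiasmatic genes, glial, vascular, ependymal, choroid plexus and blood cell markers, markers of neighbouring brain regions, glucocorticoid-regulated, NFAT5-regulated and heat shock genes, ribosomal protein and respiratory chain genes, non-coding RNAs and sex check genes. Lists with at least 3 measured genes were tested with limma's camera at its preset correlation and again with an estimated one, adjusted over lists within a comparison. With an estimated correlation, camera takes its degrees of freedom from the residuals, of which the fit of the ratios has 2, so that a list could hardly pass that test there. In that fit the estimated correlation was 0.33 for ribosomal protein, 0.20 for respiratory chain, 0.33 for ependymal, 0.46 for blood cell and 0.87 for endothelial genes. For such lists the p-values at the preset correlation may be too small. It was 0.02 for immediate early genes and below 0 for some other lists. Limma's fry, run as an alternative, tests whether the genes of a list move, on balance, in one direction, and does not compare them with other genes. Non-coding RNAs (2 measured, Gas5 and Snhg11) got values only.

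The rule for named genes was also fixed then. For the ratio of salt against control it takes up to 10 genes each way, and for other comparisons up to 5, by size of change among those that passed with both samples of one group beyond both of the other, or both on 1 side of 0. Where fewer than 5 passed, genes with unadjusted p under 0.01 fill up to 5 and are said not to pass. List members that passed when adjusted over the list alone are added, at most 6 per list, and 5 genes (Fos, Avp, Oxt, Crh and Pdyn) always. Of these, the text gives examples per list. Other genes are said to have been chosen after their values were seen.

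Alternatives covered background correction, scaling, the filter on dim probes, the deposited ratios, 1 probe per gene, the empirical Bayes step, the samples in the fit, a replicate block and leaving out each sample. The fits were tested on simulated data of 14199 probes, of which 67 were changed by 2-fold, 67 by 4-fold and 66 by 8-fold. For the ratio of salt against control, 16.4% of probes changed by 2-fold, 86.6% of those changed by 4-fold and 100% of those changed by 8-fold were recovered. For the IP level of salt against control these shares were 61.2%, 98.5% and 100%. Of the unchanged probes, 12 were called for that ratio, 16 for the IP level, 4 for the input level, 7 for IP against input of control and 11 for that of salt. The simulation had no normalization step, and its many changed probes loosened the adjusted threshold. In the real ratio of salt against control, Avp missed the threshold at a log2 difference of 3.26, over 8-fold. The recovered shares therefore do not give the power of the real comparisons. The number of arrays limits the precision. Where a statement rests on gene span, the start-to-end length of the gene in the names table was used, since transcript lengths were not used here.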

Results

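The RNA of phosphorylated ribosomes and total RNA were profiled in the hypothalamus of mice given hypertonic salt or vehicle, with 2 samples per group and an IP and an input array for each. S6 is a protein of the small ribosomal subunit that becomes phosphorylated in active neurons, so an antibody against the phosphorylated form pulls down ribosomes, with their mRNA, preferentially from such cells. Median intensities ranged from 143.3 to 161.9 and 12259 to 13808 of 25697 probes were detected per array, 13058 to 13808 on IP arrays and 12259 to 12705 on input arrays. Across the tested probes, the log2 IP/input ratios of the control samples correlated at r = 0.87 and those of the salt samples at r = 0.73, and salt replicate 2 had the narrowest ratios (SD 0.59 against 0.64 to 0.71 in the other samples). Genes are not independent replicates, so these r values only describe the arrays.

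The ratio of IP to input, salt against control, asked which mRNAs were recovered more or less with phosphorylated ribosomes after the osmotic stimulus, relative to total RNA. Avp, which encodes the antidiuretic hormone vasopressin, had the largest difference among the named genes. Its ratio went from a log2 mean of -1.86 in control (SD 0.46) to 1.40 in salt (SD 0.48), a difference of 3.26 ± 0.32 (SE) or 9.57-fold, with every salt sample above 0 and every control sample below 0. Avp missed the threshold over all probes (adjusted p = 0.118) and passed when adjusted over the list alone (9.13e-05). Oxt, which encodes oxytocin, the other hormone of the magnocellular neurons, differed by 1.27 ± 0.22 (adjusted over the list alone, 0.0041). It stayed below 0 in both groups, at -1.86 in control and -0.59 in salt. The immediate early genes Fosb (1.32 ± 0.27) and Fos (1.16 ± 0.24), transcription factor genes induced by neuronal activity, also passed over their list alone (0.0243 each). Crh, the stress hormone precursor gene, differed by 0.85 ± 0.25 and Pdyn, the dynorphin precursor gene, by 0.42 ± 0.27, and neither passed in either way. Crh was undetected on both control IP arrays.

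Of the 14199 probes, 0 passed in limma, with 388 at an unadjusted p under 0.05 (204 higher, 184 lower). The other genes taken by the fallback rule did not pass either. They were Fezf2 (1.26 ± 0.29) and Amer1 (1.20 ± 0.24, undetected on both salt input arrays) on the higher side. On the lower side they were Elf1 (-1.17 ± 0.22), Ago4 (-1.15 ± 0.28), 1700017N19Rik (-0.96 ± 0.25), Zfand2b (-0.93 ± 0.25) and Mip (-0.90 ± 0.24), each undetected on both control input arrays. Salt and control samples did not overlap for 26.8% of probes, against 33.3% by chance. Avp alone passed in 7 alternatives, among them the deposited ratios (2.51 ± 0.22, adjusted p = 0.00147) and the fit with the replicate block (adjusted p = 0.0263), the adjusted p ranging from 1.42e-04 to 1.00 over all alternatives. Without salt replicate 1, 16 probes passed, Avp among them, and without salt replicate 2 Avp alone.

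**Figure D1:**
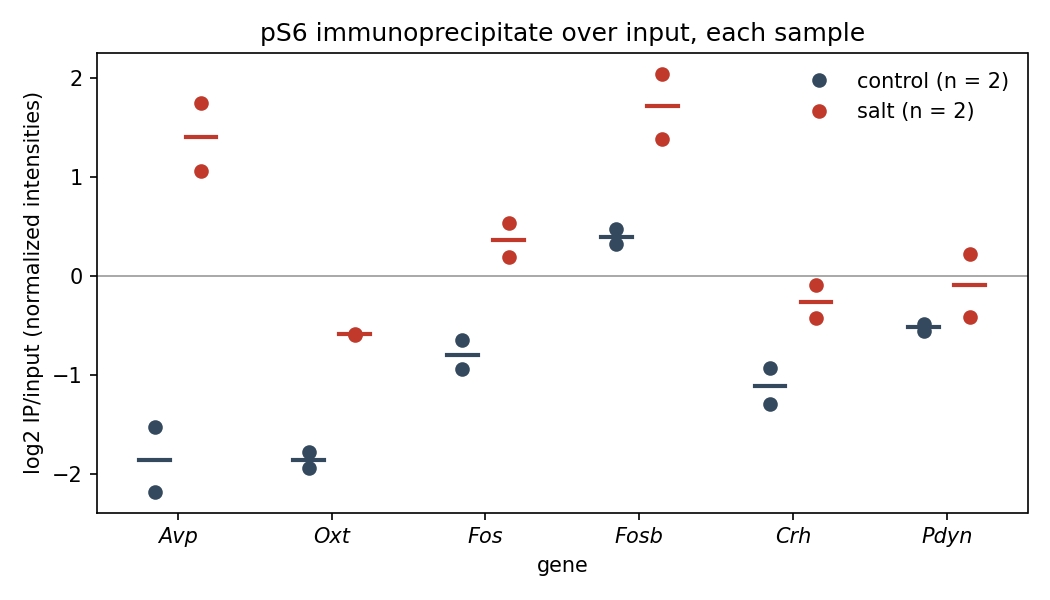
Log2 IP/input (vertical axis, normalized intensities) of 6 genes in each control and salt sample; points are samples (n = 2 per group) and bars are group means. Avp sits at -1.86 on average in control and 1.40 in salt, while Pdyn averages -0.52 in control and -0.10 in salt, where its samples lie at -0.42 and 0.23.

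In the list test, the immediate early genes had a median difference of the ratio of 0.38 and 30 of 34 measured members lay above 0, with 0 passing over all probes and 2 over the list alone (camera adjusted p = 6.94e-11). The magnocellular list had a median of 0.12 and a mean of 0.39 (SD of members 0.79) over 20 genes (9.66e-05), with Avp and Oxt passing over the list alone. Of its members 14 lay above 0. Camera tests a mean over members and not the median, so a few genes with large differences, such as Avp, can carry a call. Microglia markers had a median of -0.30 over 8 genes (0.0379), blood cell markers -0.48 over 3 genes (0.00886) and oligodendrocyte markers 0.12 over 15 genes (0.049). With an estimated correlation none of these 5 calls held, at adjusted p = 0.55 for immediate early genes and 0.567 for the other 4 lists. With 2 residual degrees of freedom a list could hardly pass that test, so the loss says little about the calls. The estimate itself was 0.02 for immediate early genes, -0.12 for microglia and -0.02 for oligodendrocyte markers. The immediate early gene median was 0.21 with no background correction and 0.23 both with normexp without negative controls and with probes detected on all arrays, with the call kept. The microglia call was lost with probes detected on all arrays (0.106) and in the deposited ratios (median -0.12, 0.068), and the median was -0.18 with no background correction. The oligodendrocyte call was lost with median scaling (0.056), with probes detected on all arrays (0.106) and with the mean of all probes of a gene (median 0.08, 0.0748). The magnocellular median was 0.35 without salt replicate 1, 0.01 without salt replicate 2, which ended its call (0.283), 0.25 without control replicate 1 and 0.20 without control replicate 2. Without salt replicate 2 the calls of the blood (-0.36), microglia (-0.14) and oligodendrocyte (0.21) lists were lost as well; those 3 were also lost without control replicate 2 (-0.29, -0.31 and 0.14), and the oligodendrocyte call without salt replicate 1 (0.21), its median being 0.24 without control replicate 1. The remaining 18 tested lists, neuronal, astrocyte, endothelial and respiratory chain genes among them, did not pass.

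The IP level itself, salt against control, showed a rise of 19 probes of 19 genes and a fall of 0. The steepest rise was that of Fosb, by 4.28 ± 0.20 on the log2 scale or 19.5-fold (adjusted p = 4.61e-05). Cxcl1, a chemokine gene, rose by 3.44 ± 0.47 (0.0328), Avp by 3.41 ± 0.36 or 10.6-fold (0.0127) and Fos by 3.15 ± 0.40 or 8.87-fold (0.0225). Cxcl1 and Fos were detected on 1 of the 2 control IP arrays, and their rise was 4.37 and 3.77 without control replicate 1 and 2.503 and 2.53 without control replicate 2. Gem, which encodes a small GTP-binding protein, was undetected in control and rose at least 3.95-fold (0.0031). Of the 34 immediate early genes, 11 rose and 33 lay above 0, with 20 passing over the list alone, and the list median was 0.82, or 0.61 with 6 members undetected in a group set at their bound. Among them were Maff (1.93 ± 0.19), Klf4 (1.85 ± 0.23), Btg2 (1.73 ± 0.24) and Egr4 (at least 1.63-fold, undetected in control). The list's shift held with an estimated correlation (adjusted p = 4.58e-40 with the preset one and 0.00226 with the estimated one), and the median was 0.51 with no background correction and 0.40 with probes detected on all arrays.

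In the same comparison, glucocorticoid-regulated genes had a median of 0.45 over 16 genes, or 0.35 with bounds, and 2 rose over all probes and 7 over the list alone (camera adjusted p = 1.52e-10, and adjusted p = 0.0501 with an estimated correlation). Sgk1, a kinase gene that responds to corticosteroids and to cell volume, rose by 2.05 ± 0.24 and the phosphatase gene Dusp1 by 1.27 ± 0.17. Dusp1 and Per1 are also members of the immediate early list, and Dusp1 is counted among the genes of that list that rose. The calls of the glucocorticoid and immediate early lists are thus not fully independent. In the magnocellular list Avp rose and 5 of 20 genes passed over the list alone. The others were Crh (at least 1.30-fold, undetected on the control IP arrays), Oxt (1.05 ± 0.28), Gal (0.76 ± 0.24) and Pcsk1 (0.93 ± 0.27), the gene of a prohormone-cleaving protease. Without salt replicate 2 Gal was at 0.44 and Pcsk1 at 0.58. Its median was 0.26, or 0.23 with bounds (2.37e-06, and adjusted p = 0.281 with an estimated correlation). Other neuropeptides (median 0.25, or 0.15 with bounds, 0.00113), NFAT5-regulated osmoprotective genes (0.12, 0.0068), monoaminergic genes (0.25, 0.0152) and endothelial markers (0.34, or 0.21 with bounds, 0.0168) passed with the preset correlation and not with an estimated one (adjusted p between 0.356 and 0.555). In the microglia list, P2ry12 (at least 1.45-fold lower, undetected on both salt IP arrays) and Aif1 (-0.75 ± 0.20) passed over the list alone, while 0 of 8 passed over all probes, 3 lay above 0 and the list did not pass (median -0.04, camera adjusted p = 0.16). The endothelial median was 0.90 without salt replicate 1 and 0.52 without control replicate 1, and turned to -0.17 without salt replicate 2 and -0.02 without control replicate 2. With probes detected on all arrays the endothelial (0.17, 0.311) and other neuropeptide (0.17, 0.127) calls were lost, and with no background correction these medians were 0.20 and 0.16. Calls were lost for monoaminergic genes without salt replicate 1 (0.25) or control replicate 1 (0.20), for NFAT5-regulated genes without salt replicate 2 (0.03), and for other neuropeptides without salt replicate 2 (0.13) or control replicate 1 (0.13). Medians moved by over 1.5 times with the call kept for magnocellular genes without salt replicate 1 (0.47), salt replicate 2 (0.16) or control replicate 2 (0.40), for monoaminergic genes without salt replicate 2 (0.45) or control replicate 2 (0.47), and without salt replicate 1 for NFAT5-regulated genes (0.22) and other neuropeptides (0.48).

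The other 8 of the 19 genes, named after their values were seen, were Egr1 (1.60), Nr4a1, Nr4a3, Csrnp1, Rrad, Rgs1, Mfsd2a (1.45) and Cdkn1a, whose passing probe was not its brightest. On the lower side Plk4 (at least 1.79-fold), Dsc2, Wdr5b, Mip (-1.12 ± 0.18) and Ppp1r1b (-1.01 ± 0.22) were taken by the fallback rule and did not pass, with adjusted p of 0.0659 or more. Plk4 and Dsc2 passed with median scaling (adjusted p = 0.0417 for each), with IP and input arrays quantile-normalized apart (0.0435) and with 1 probe per gene (0.0475), the adjusted p reaching 0.618 for Plk4 and 1.00 for Dsc2 over all alternatives. The count fell to 1 without salt replicate 1 or without salt replicate 2 (Fosb both times), to 5 without control replicate 1 and to 3 without control replicate 2. It was 2 with no filter on dim probes, 7 with probes detected on all arrays and 10 with the IP arrays fitted alone. Of the 11 called values of named genes in this comparison, 5 were over 1.5 times smaller with no background correction, with no call lost.

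**Figure D2:**
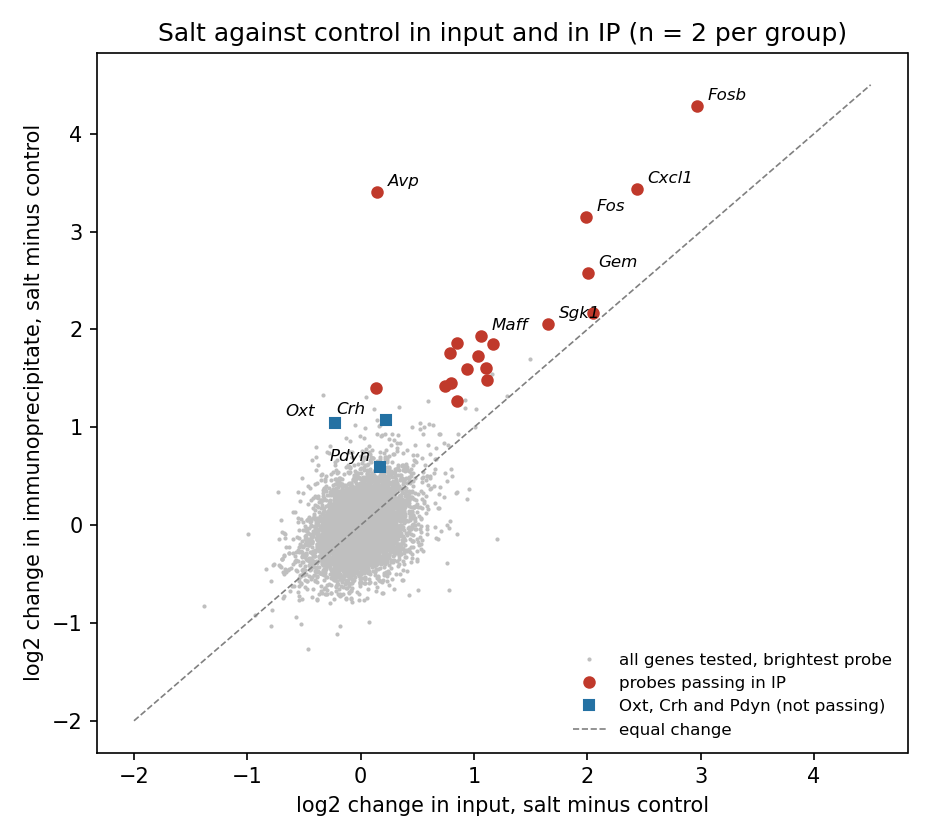
Log2 change of each gene after salt in total RNA (horizontal axis) and in the IP (vertical axis), salt minus control, n = 2 per group; grey points are the brightest probes of the tested genes, red points the 19 probes that passed in the IP, blue squares Oxt, Crh and Pdyn, and the dashed line marks equal change. Fosb lies high on both axes (2.97 and 4.28), and Avp on the vertical one (0.15 and 3.41).

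Total RNA, salt against control, changed for 2 probes, both higher. Fosb rose by 2.97 ± 0.20 or 7.82-fold (adjusted p = 0.00129) and Gem at least 2.78-fold (0.0275). Fosb was detected on 1 of the 2 control input arrays, and its rise was 2.05 with no background correction. Fos (1.99 ± 0.40), Cxcl1 (at least 2.56-fold, undetected in control) and Sgk1 (1.66 ± 0.24) did not pass over all probes. Sgk1 passed with no background correction (adjusted p = 0.0199), normexp without negative controls (0.0163), median scaling (0.0462) and trend and robust empirical Bayes (0.00433). Fos passed with no background correction (0.0368). Neither passed under the other alternatives that kept all samples. The hormone genes did not pass in the input, with 0.15 ± 0.36 for Avp, -0.22 ± 0.28 for Oxt, 0.23 ± 0.25 for Crh and 0.17 ± 0.21 for Pdyn. Of the immediate early genes, 1 rose over all probes and 17 of 34 over the list alone, Egr2 (2.83-fold) and Klf4 (1.17 ± 0.23) among them. Their list median was 0.52, or 0.29 with 6 members at their bound, and the shift held with an estimated correlation (camera adjusted p = 2.61e-34 with the preset one, 0.00309 with the estimated one), and the median was 0.33 with probes detected on all arrays.

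Glucocorticoid-regulated genes were higher in total RNA too, with a median of 0.44 over 16 genes and 6 passing over the list alone (4.78e-14, and adjusted p = 0.0289 with an estimated correlation). Besides Sgk1 and Dusp1 these were Cdkn1a (1.29 ± 0.33, and 0.72 without salt replicate 2), Ddit4 (0.86 ± 0.21), Errfi1 (0.56 ± 0.18) and Pdk4 (0.56 ± 0.17). NFAT5-regulated genes (median 0.28 over 9 genes, 3.48e-05) and blood cell markers (0.40 over 3 genes, 0.00389) passed with the preset correlation only (adjusted p = 0.531 for both with an estimated one). Sgk1 is a member of both the glucocorticoid and the NFAT5 list, and the 1 NFAT5-list gene that passed over that list alone. Dusp1 is a member of both the glucocorticoid and the immediate early list. On the lower side H1f4 (-1.39 ± 0.19), Trim59, Zfp41, Zfp300 and Hdhd3 were taken by the fallback rule and did not pass, with adjusted p of 0.135 or more. H1f4 passed with no background correction (adjusted p = 0.0368), normexp without negative controls (0.0316) and median scaling (0.0474), the adjusted p reaching 1.00 over all alternatives. At an unadjusted p under 0.05 there were 342 probes. No probe passed without salt replicate 1, without salt replicate 2 or without control replicate 2, and 3 passed without control replicate 1, Fosb among them. The blood cell call was lost without salt replicate 1 (0.38) or control replicate 2 (0.19), and its median was 0.75 without control replicate 1. The NFAT5 median was 0.48 without salt replicate 1 and 0.12 without salt replicate 2, with the call kept.

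IP against input in control animals asked which mRNAs the antibody enriched at baseline. Of 14199 probes, 2823 were higher and 2854 lower in the IP, 1038 and 550 of them by 2-fold or more. Hivep2, a zinc-finger factor gene, was at least 6.18-fold higher, Helq, a DNA helicase gene, at least 5.89-fold and Zzef1 at least 3.69-fold, all undetected in the control inputs. Sec24d, a coat protein gene of vesicles leaving the endoplasmic reticulum, was higher by 2.71 ± 0.18 and Atp8b1 by 2.57 ± 0.26. Lower in the IP were Onecut2 (-2.80 ± 0.22), Dynlrb2 (-2.54 ± 0.26), Efhd1 (-2.23 ± 0.20), Lrrc29 (undetected in the control IPs) and Agrp (at least 3.36-fold), the gene of a feeding peptide of the arcuate nucleus.

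The other neuropeptides had the lowest median of the tested lists in control in the main fit. Ependymal markers lay lower with no background correction and with normexp. In control replicate 2 the choroid plexus median was lower (-0.94 against -0.89). Of 18 other neuropeptides 12 were lower and 2 higher, over all probes and over the list alone, with a median of -0.85, or -0.74 with 7 members at their bound (camera adjusted p = 0.00394). Npy was at least 3.37-fold and Ghrh at least 2.52-fold lower, Nts differed by -1.51 ± 0.24 and Sst by -1.33 ± 0.18, while Vip was higher by 1.52 ± 0.16. In the magnocellular list 7 of 20 were lower and 0 higher, with Oxt at -1.86 ± 0.15, Avp at -1.86 ± 0.23 and Gal at -1.79 ± 0.17, and the list as a whole did not pass (0.139). Respiratory chain genes (36 of 65 lower, median -0.50, 2.27e-07), cytosolic ribosomal protein genes (21 of 56 lower, -0.33, 2.04e-04), ependymal markers (5 of 8 lower, -0.81 or -0.61 with bounds, 0.0118) and microglia markers (4 of 8 lower, -0.43, 0.0426) passed as lower lists. Adjusted over the list alone, 38, 20, 5 and 4 of these genes were lower. All 3 measured blood cell genes were higher (median 1.20, 0.0235), Hba-a1 by 1.63 ± 0.25. None of these 6 list calls held with an estimated correlation (adjusted p = 0.658 for each), and the microglia call was lost without control replicate 1 (-0.37) and under each other scaling and background correction (0.0549 to 0.0661), in the deposited ratios (0.0651) and with probes detected on all arrays (0.14), a filter that also ended the neuropeptide call (0.0563). A list could hardly pass with an estimated correlation, given 2 residual degrees of freedom. The ribosomal median was -0.22 without control replicate 2, with the call kept. Of 34 immediate early genes 5 were higher and 9 lower, over all probes and over the list alone, and the list did not pass (median -0.06, or 0 with 7 members at their bound, 0.718). Arc was higher by 2.07 ± 0.16 and Gadd45g by 1.57 ± 0.15, while Egr1 differed by -0.93 ± 0.17 and Fos by -0.80 ± 0.17. Among single genes of other lists, Gpr17, a marker of oligodendrocyte precursors, was higher by 1.78 ± 0.18.

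IP against input in salt-treated animals gave 2664 probes higher and 2569 lower, 847 and 479 of them by 2-fold or more. Hivep2 (at least 6.16-fold), Sec24d (2.60 ± 0.18), Dicer1 (2.49 ± 0.22), which encodes a microRNA-processing enzyme, Helq (at least 4.56-fold) and Hira (2.46 ± 0.27, and 1.87 and 3.05 without salt replicates 1 and 2) led the higher genes. Lrrc29 (at least 4.70-fold), Onecut2 (-2.22 ± 0.22), Dynlrb2 (-2.05 ± 0.26), Efhd1 (-1.92 ± 0.20) and the histone gene H2bc4 (-1.90 ± 0.23) led the lower ones. Avp was higher in the IP here, by 1.40 ± 0.23 (adjusted p = 0.00414), Fosb by 1.71 ± 0.19 and Per1, a clock gene, by 1.29 ± 0.21. Oxt differed by -0.59 ± 0.15 (0.021, and 0.055 without either control sample), and Fos (0.36 ± 0.17), Crh (-0.26 ± 0.17) and Pdyn (-0.10 ± 0.19) did not pass.

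By list, 11 of 34 immediate early genes were higher and 3 lower in the salt IP, and the list did not pass (median 0.27, camera adjusted p = 0.0656). Other neuropeptides (14 of 18 lower, 3 higher, median -0.72 or -0.66 with bounds, 0.00377), respiratory chain genes (35 of 65 lower, -0.51, 2.14e-08), ribosomal protein genes (19 of 56 lower, -0.35, 8.12e-05), ependymal markers (5 of 8 lower, -1.02 or -0.79 with bounds, 0.00496) and microglia markers (6 of 8 lower, -0.86, 0.00377) passed as lower lists, and none held with an estimated correlation (adjusted p = 0.631 for each). Adjusted over the list alone, 14, 37, 18, 6 and 6 of these genes were lower. As in control, a list could hardly pass with an estimated correlation, given 2 residual degrees of freedom. P2ry12, a microglial receptor gene, was at least 3.08-fold lower and Npy differed by -1.69 ± 0.17, or -0.93 with no background correction and -0.84 in the deposited ratios. Of the called values of named genes, 36 of 95 in control and 36 of 93 in salt were over 1.5 times smaller with no background correction, and 41 and 40 in the deposited ratios, the call being lost for 2 and 5 and for 3 and 5 of the called values. Both IP-against-input splits moved with the scaling. With arrays scaled to a common median they were 2332 higher and 3852 lower in control and 2160 and 3717 in salt, the median of all probes being -0.16 and -0.15. With IP and input arrays quantile-normalized apart they were 3476 and 2364 in control and 3378 and 2131 in salt. Less the median of all genes, other neuropeptides lay between -0.82 and -0.42 in control over these scalings and the background corrections, and respiratory chain genes between -0.66 and -0.44. With no background correction, with normexp and in the deposited ratios, ependymal markers had medians of -0.45, -0.52 and -0.39 in control and -0.47, -0.57 and -0.40 in salt, and other neuropeptides -0.44, -0.49 and -0.45 in control. With median scaling, ribosomal protein genes lay at -0.67 in control and -0.69 in salt and respiratory chain genes at -0.82 and -0.88. The microglia median of salt was -0.49 in the deposited ratios. In control the count was 1497 without control replicate 1 and 1063 without control replicate 2.

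**Figure D3:**
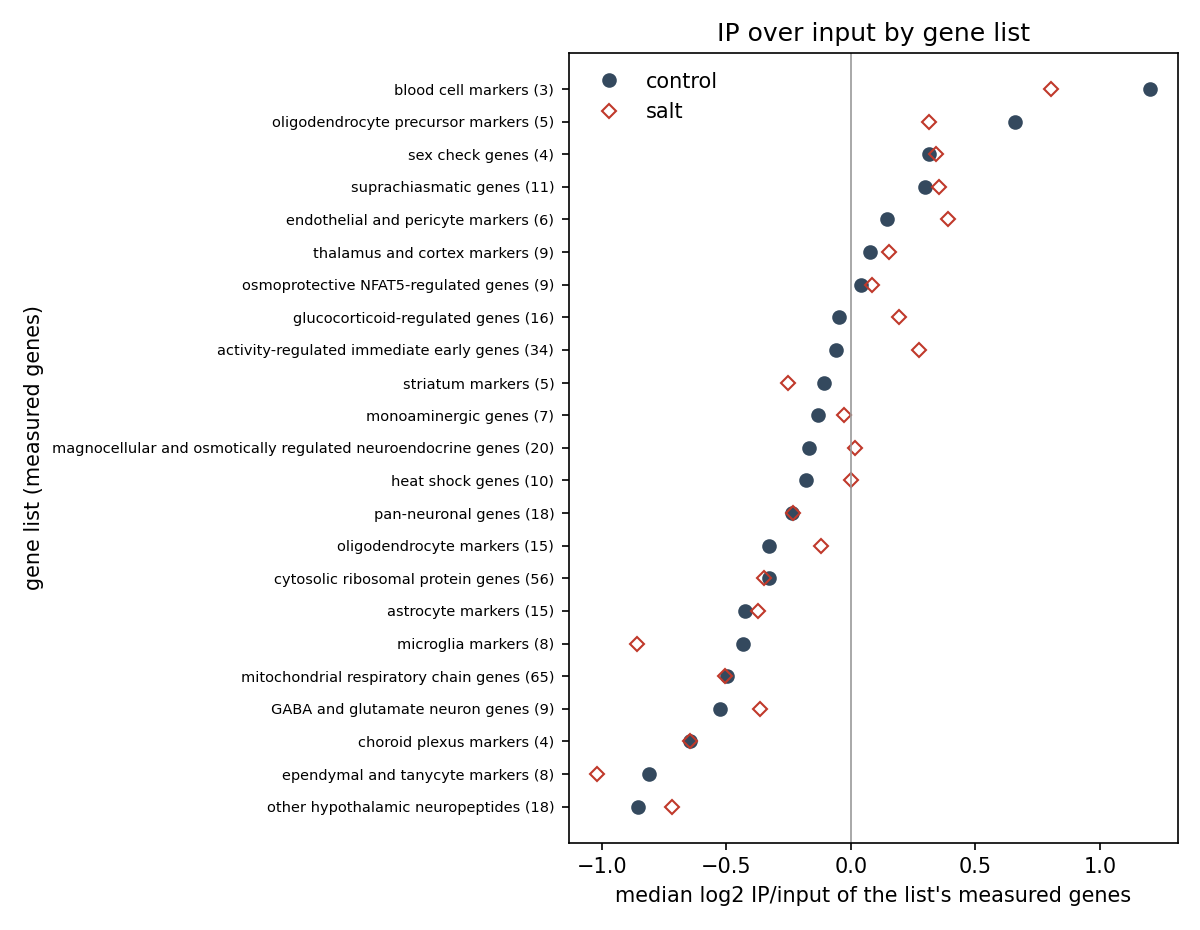
Median log2 IP/input of the measured genes of each list (horizontal axis) in control (filled circles) and salt samples (open diamonds), with the number of measured genes in brackets. Other neuropeptides sit at -0.85 and -0.72, and immediate early genes at -0.06 in control and 0.27 in salt.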

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

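The tests of explanations in this part were chosen after the results they bear on were seen. Vasopressin and oxytocin mRNA had large differences between the groups, although neither passed over all probes for the ratio of salt against control. Avp passed under some alternatives and Oxt under none. Avp lay above 0 in IP/input in each salt sample and below 0 in each control sample, with a difference of 3.26 on the log2 scale, and Oxt differed by 1.27. More Avp and Oxt tissue in the salt dissections would raise input as far as IP. Within 2 SE the input change reached at most 0.87 for Avp and 0.33 for Oxt. These lay below the lowest IP changes of 2.68 and 0.49, the difference being at most -0.16. The comparison restates the ratio difference for which these genes were flagged, so it is no separate test of that explanation. The 2 salt inputs also differed for Avp (SD 0.81), and its input change ranged from -0.42 to 0.72 over the alternatives. Another background correction or scaling, or the deposited ratios, left the smaller of their ratio changes at 5.24 SE or more above 0, and leaving out any single sample at 3.37 SE or more. The salt treatment is what the design compares. Chance, handling and an unrecorded batch that differed between the groups were not tested for these genes, and they stay open as well.

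The immediate early genes differed in the ratio by a median of 0.38, a difference between groups called by camera at its preset correlation and not with an estimated one (adjusted p = 0.55), and rose in IP and in input. With 2 residual degrees of freedom a list could hardly pass with an estimated correlation in the ratio. Array scaling or background correction is argued against, since under each of them the list median, less that of all genes, lay at least 4.36 SE (spread of the members) above 0 in input and IP. How far the IP rose beyond the input is the ratio itself, with list medians of 0.20 and 0.31 in the salt samples and -0.10 and -0.13 in the control samples, a difference that fry did not call (adjusted p = 0.203). Handling stress that differed between the groups stays open: heat shock genes had a median input change of 0.083, 2.18 SE of the members above 0, but their mean of 0.060 lay at 1.57 SE, camera did not call the list (adjusted p = 0.577), and the median lay far below the 0.52 of the immediate early genes. The salt treatment is the explanation the design names, and it is not separated from handling here.

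Blood cell markers differed in the ratio by a median of -0.48, magnocellular genes by 0.12, microglia markers by -0.30 and oligodendrocyte markers by 0.12, each called by camera at its preset correlation and not with an estimated one. The latter test could hardly be passed here either. Of the genes named for the ratio of salt against control, 4 more had each salt sample on the other side of 0 from each control sample. The difference did not pass in limma: Amer1 at 1.20, Fos at 1.16, 1700017N19Rik at -0.96 and Elf1 at -1.17. Genes beyond those named were not screened by this rule, and Dusp1, for example, also met it (mean ratios of 0.10 in salt and -0.32 in control). Amer1 was undetected on both salt input arrays, and 1700017N19Rik and Elf1 on both control input and both salt IP arrays, so their side of 0 rests on probes not above background, and their deposited differences were 0.65, -0.37 and -0.45.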

How the results depend on the processing

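The crossed block and the ratios scaled to 1 spread were chosen after seeing the data. For the ratio of salt against control, 1 probe (Avp) in place of 0 passed with no background correction, normexp without negative controls, probes detected on all arrays, the deposited ratios (both tables being identical), trend and robust empirical Bayes, the replicate block and ratios scaled to 1 spread, and 0 to 16 passed without each sample in turn. Input calls, 2 before, numbered 7 with no background correction, 5 with normexp, 5 with median scaling, 5 with trend and robust, 1 with no filter, 0 with probes detected on all arrays, 1 with the input arrays alone and 0 to 3 without each sample. IP calls, 19 before, numbered 2 with no filter, 7 with probes detected on all arrays, 10 with the IP arrays alone and 1 to 5 without each sample. IP against input in control ranged from 1063 to 7700 calls without each sample, and no alternative moved the salt count by over 1.5 times. Fewer samples, or another number of probes, changed these tests by construction; the cause of the other shifts was not tested. Whether replicate numbers pair samples across groups is not known. Same-numbered deviations correlated at 0.01 for ratios, -0.23 for input and 0.14 for IP, which with 2 samples per group cannot decide it. The replicate block gave 1 input call and 14 IP calls, and the crossed block 2 input calls. Of called lists, the estimated correlation left 0 in the ratio of salt against control, 0 and 0 in IP against input of control and salt, 2 in input and 1 in IP; fry, which compares no list with other genes, called 0 in the ratio, 6 in IP against input of control (of the 6 of camera, neuropeptides and microglia markers), 8 in that of salt (of the 5 of camera, these and respiratory chain genes), 2 in input and 2 in IP. Changes of sign were few: Pdyn in IP against input of salt was 0.23 without salt replicate 1, Avp in input ranged from -0.42 (without salt replicate 2) to 0.72, Oxt in input from -0.50 to 0.056 (without salt replicate 1; 0.048 without control replicate 1), and the endothelial list in IP from -0.17 (without salt replicate 2; -0.02 without control replicate 2) to 0.90, without each sample in turn. Without a sample its group has 1 left, which is assumed to vary like the others. Of the named genes under all alternatives, 3761 values kept their side of the threshold, 308 lost and 95 gained a call. Of called lists, 264 values kept and 72 lost the call. These include the estimated correlation, with which a list could hardly pass in the fit of the ratios. Files name no slide, so a slide block was not run. Signal over background limits what can be seen, with 47.7% to 53.7% of probes detected per array.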

Other observations

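Of the suprachiasmatic list, the genes of the circadian pacemaker nucleus, 3 of 11 measured were higher and 2 lower in the control IP than in input, and 5 were higher and 1 lower in the salt IP. Avp, also counted in the magnocellular list, is among the lower genes in control and the higher ones in salt. The others include Vip at 1.52 ± 0.16 and 1.43 ± 0.16, Rgs16 at 1.07 ± 0.16 and 0.55 ± 0.16, and Per1 at 1.29 ± 0.21 in salt. Grp was lower in both, at least 1.38-fold in control and 1.54-fold in salt. The list did not pass as a whole (camera adjusted p = 0.315 and 0.162). Mice were killed at about circadian time 6, per the labels. Of 5 oligodendrocyte precursor markers 4 were higher and 1 lower in the control IP and 2 and 1 in the salt IP, with Gpr17 at 1.78 ± 0.18 and 1.71 ± 0.18 and Olig1 lower. Of 15 oligodendrocyte markers 1 was higher (Ugt8a, 1.16 ± 0.17 and 1.59 ± 0.17) and 5 lower in each, Ermn (-2.10 ± 0.18 and -1.52 ± 0.18) and Mog (-1.15 ± 0.19 and -0.75 ± 0.19) among them. Neither list passed with camera (adjusted p = 0.119 and 0.339 for precursor markers, 0.119 and 0.393 for the others). Fry called precursor markers in both groups (adjusted p = 0.00717 and 0.0141) and oligodendrocyte markers in control (0.0272). Of the metallothionein genes, Mt2 was lower in both IPs (-1.06 ± 0.16 and -1.46 ± 0.16, or -0.57 and -0.74 in the deposited ratios). Mt1 lay between -1.79 and -0.32 in control and between -1.37 and -0.97 in salt over the alternatives. It passed under some of them only. In control, the calls of Mt2 (0.0793), Ugt8a (0.0649) and Rgs16 (0.0605) were lost without control replicate 2 and that of Mog (0.0916) without control replicate 1. In salt, that of Rgs16 was lost without salt replicate 2 (0.37) and with median scaling (0.39). In the authors' deposited table the probe with the highest salt over control ratio was that of Avp (5.78), followed by Fosb (2.52), Cxcl1 (2.01) and Oxt (1.93).

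The remaining lists did not pass with camera in IP against input of either group. Their medians in control and salt were -0.42 and -0.37 for 15 astrocyte markers, -0.65 and -0.65 for 4 choroid plexus markers, -0.53 and -0.37 for 9 GABA and glutamate neuron genes, and -0.24 and -0.23 for 18 pan-neuronal genes. They were 0.15 and 0.39 for 6 endothelial markers (0.0084 and 0.047 with bounds), -0.13 and -0.03 for 7 monoaminergic genes, -0.11 and -0.25 for 5 striatum markers, 0.08 and 0.15 for 9 thalamus and cortex markers (0 and 0.079 with bounds), and 0.31 and 0.34 for 4 sex check genes. Heat shock genes (10 measured) had medians of -0.18 and -0.0015, and 0.13 in the IP level of salt against control (camera adjusted p = 0.0658). Of the remaining lists, fry called choroid plexus markers in control and salt (adjusted p = 0.0143 and 0.0141) and pan-neuronal genes in control (0.0443). In salt it also called GABA and glutamate neuron genes and glucocorticoid-regulated genes (0.0493 each). Of genes outside a testable list, Gas5 was at 0.62 ± 0.17 in control and 0.63 ± 0.17 in salt (adjusted p = 0.0207 and 0.0216), and the call was lost in both with median scaling (0.19 and 0.18, adjusted p = 0.385 and 0.413) and with IP and input arrays quantile-normalized apart (0.41 and 0.40). It was also lost in control without either control replicate (0.56 and 0.69), and in salt without salt replicate 1 (0.45). Snhg11 was at -0.48 ± 0.16 in control, a call lost without control replicate 1 (-0.63) or 2 (-0.34), and did not pass in salt (-0.41 ± 0.16); with median scaling it passed in both (-0.90 and -0.86).

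The test of random lists was set before its result was seen, and the scaling tests after. Genes of a longer span were relatively higher in the IP: across 9740 genes, which are not independent, span and log2 IP/input had a Spearman rho of 0.33 in control and 0.33 in salt, with medians of -0.41 and -0.39 in the decile of the shortest genes and 0.24 and 0.21 in that of the longest. For the cytosolic ribosomal protein genes, gene span and expression level may account for the shift, since their median lay at up to the 37.5th percentile of 10000 random lists matched on both. For the other neuropeptides and the respiratory chain genes, the medians lay below all matched random lists in both groups (percentile 0). In control they were -0.85 and -0.50, against medians of -0.22 and -0.21 over the matched lists. Members of random lists were drawn 1 by 1, so such lists lack the correlation of a real list. It was estimated at 0.02 for neuropeptides and 0.20 for respiratory chain genes. For the latter, percentile 0 may overstate how far the list lies beyond span and level. Array scaling or background correction left the neuropeptide, respiratory chain and ribosomal protein lists below the median of all genes. The position nearest to 0 was -2.70 SE of the members for neuropeptides, -12.7 SE for respiratory chain genes and -6.83 SE for ribosomal protein genes. This SE treats members as independent. With estimated correlations of 0.20 for respiratory chain and 0.33 for ribosomal protein genes, it is too small for those lists, and their positions in SE are overstated. Span stands in for transcript length, which was not used here, and no biological explanation was tested.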
